A study of Homo sapiens with 45 samples.

How the data were processed

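Poised-enhancer capture Hi-C libraries from HNES1 cells were compared on day 5 of the naive-to-primed transition after DMSO, UNC6852 at 2.5 µM or UNC1999 at 1 µM, present from 24 h before day 0. The doses differ between the compounds, so the compounds are not compared as to strength. Each condition had 15 libraries from 3 biological replicates, sequenced in 2 batches, and was represented by 1 column pooled over all of them.

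Each deposited value is a CHiCAGO score, a measure of how far the reads joining a bait and another fragment exceed a background model, per the file headers and the labels, which name the pooled column of each condition. Per the submitters' processing notes the genome build is GRCh38. Versions and settings of the aligner and the caller were not given in the sources used here. From the values, scores were never negative, all 434524 listed pairs reached 5 in at least 1 column, and the columns were not scaled to each other. Read numbers behind the scores were unknown, so no depth, detection floor or read-based interval is given. Intervals on shares of calls are exact (Clopper-Pearson) 95% binomial intervals over the called pairs and cover counting error only.

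From these scores, a pair was called in a profile at a score of 5 or more. Differences were taken between asinh-transformed scores, with no folds, since many scores are 0. Shares of calls of a profile also called in another were computed in both directions, and UNC6852 against UNC1999 served as the reference for how far 2 pooled profiles differ. Pairs were classed by distance (breaks at 20, 100 and 500 kb and 2 Mb, and trans) and by the other end, which was another captured fragment, a fragment within 1000 bp of an end of a protein-coding gene, or neither. For the matched comparison, pairs were grouped by distance class and deciles of mean score.

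Genes came from the RefSeq annotation of GRCh38.p14, which placed 19987 protein-coding genes. The plan named transcription starts, but the table used gives no strand, so a pair was assigned to a gene when its bait or other end reached within 1000 bp of either annotated end. Genes with at least 3 cis pairs numbered 4979. The 10 gene lists held 452 genes, all matched, 2 of them by an older symbol, and 20 symbols stood in more than 1 list. A list's median difference was placed among 10000 random lists of the same size, matched in quintiles of mean score and in 3 classes of pair number (1 to 2, 3 to 9, 10 or more), or 2000 random lists for the alternatives. Such percentiles are descriptive. The 10 lists and 3 contrasts made 30 comparisons.

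Genes to name were set by rule for each compound: the 10 with the lowest and the 5 with the highest difference among genes with at least 5 cis pairs and a mean score above the median of such genes, and from each list the 2 lowest and the 1 highest for UNC6852 among genes with at least 3 pairs. Single pairs to name were the 5 with the largest fall from a DMSO score of at least 10 whose other end held a gene end. Lists, comparisons, the naming rule and most alternatives were fixed before the data were examined. The strongest contacts per list, contacts between developmental genes and the comparison of neighbouring baits were added afterwards. Neighbouring baits were captured fragments at most 2 fragments apart, each more than 20 kb from the other end they shared. In 100 draws the 3 profile labels were exchanged at random in 1 of the 2 baits, anew for each comparison.

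To see what a shared DMSO profile does to the agreement of the treatments, the 3 profile labels were exchanged at random for each bait in 100 draws. The calculation was tested on simulated data. Shifts planted in 200 of the 4979 genes for UNC6852 minus DMSO came back as 0.50 for 0.5, 1.00 for 1, -0.42 for -0.5 and -0.82 for -1, the losses being damped because scores stop at 0. Shifts planted in whole lists over 20 draws with 500 random lists each are quoted with the lists. With no shift planted, 2 of 20 HOX draws lay outside the central 95%.

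Alternatives were score thresholds of 7 and 10, equal numbers of calls, merging of other ends at most 2 fragments apart, cis pairs of at least 20 kb, captured pairs counted once, and omission of the 1% of baits with most pairs (273 baits with at least 50 pairs each). Further ones were log2(score + 1), multiplied by the natural log of 2 to share the unit of asinh, quantile-normalized scores, pairs with a mean score of at least 5, gene ends within 0 or 5000 bp, genes with at least 1 or 5 pairs, the gene at the other end only, and means over baits. Gene bodies in place of ends, pairs of up to 2 Mb, and kept shares on quantile-normalized scores were added later. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Single libraries were not analysed here, since the scores are pooled.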

Results

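Poised enhancers are regulatory elements of developmental genes, among them the HOX genes, that carry Polycomb marks in pluripotent cells. Their chromatin contacts were measured in HNES1, an established line of human embryonic stem cells, on day 5 of the passage from the naive to the primed state. The assay, poised-enhancer capture Hi-C, joins DNA fragments that lie together in fixed nuclei and pulls down those that hold a poised enhancer with RNA probes. Cells received the solvent DMSO, UNC6852 at 2.5 µM, which brings about degradation of the EED subunit of Polycomb repressive complex 2 (PRC2), or UNC1999 at 1 µM, which blocks the catalytic EZH1 and EZH2 subunits. Each of the 3 conditions had 15 libraries. They came from 3 biological replicates, each with 4 technical libraries in batch 1 and 1 library in batch 2, so both batches held every condition in the same proportions. The processed values gave 1 interaction score per pair of fragments and condition, pooled over the 15 libraries. Every comparison therefore set 1 pooled profile against another, with no spread between replicates and no test, and the sequencing depth of the profiles was unknown. The assay held no measure of EED protein or of histone methylation, so the action of the compounds was not checked here.

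The profiles listed 434524 pairs of a captured fragment (the bait) with another fragment, from 27333 baits. Of these pairs, 152688 lay on the same chromosome (cis) and 281836, or 64.9%, joined different chromosomes (trans). A pair was listed only if it reached a score of 5 in at least 1 profile, and a pair at or above 5 in a profile is called in that profile. The share of listed pairs with a score of exactly 0 was 49.8% in DMSO, 46.4% in UNC6852 and 45.8% in UNC1999.

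The number of contacts was compared first, to ask whether PRC2 perturbation thinned out the poised-enhancer network. Genes of the 4 HOX clusters, with the neighbouring EVX1 and EVX2, took part in 641 called cis contacts in DMSO, 656 in UNC6852 and 614 in UNC1999. The other homeobox regulators had 594, 678 and 608 calls, in that order. Regulators of mesoderm and endoderm had 358, 411 and 369, and regulators of neural and neural crest fate had 281, 329 and 280. Genes of developmental signalling had 257, 287 and 255 calls. The subunits of Polycomb and Trithorax complexes had 83 calls in DMSO, 64 in UNC6852 and 62 in UNC1999. TFAP2C, a regulator of naive and trophoblast cells, had 26, 45 and 24. Over all cis pairs there were 64730 calls in DMSO, 70421 in UNC6852 (1.09 times as many) and 64544 in UNC1999 (0.997 times as many). Trans calls numbered 84499, 96770 (1.15 times) and 101879 (1.21 times). Among baits, 8711 had fewer cis calls in UNC6852 than in DMSO and 10480 had more, while 9542 had fewer and 9300 had more in UNC1999. Pooled profiles of unknown depth allow no statement on whether such ratios exceed those of replicates.

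The next comparison asked which contacts of the control were still called after PRC2 perturbation. HOX genes kept the highest share among the 10 gene lists: 47.3% (exact 95% interval 43.3 to 51.2) of their DMSO contacts were also called in UNC6852 and 43.7% (39.8 to 47.6) in UNC1999. Shares of the lists were not matched for distance or score. HOX genes had a median asinh score of 1.98 in DMSO, against 1.64 to 1.72 in the other developmental lists. Of the HOX contacts of UNC6852, 42.1% were called in UNC1999, and 45.0% of those of UNC1999 were called in UNC6852. The share kept from DMSO thus lay above both of these for UNC6852 and between them for UNC1999. A core of 205 HOX contacts was called in all 3 profiles. The 5 developmental lists together (HOX, other homeobox, neural, mesendoderm and signalling genes) kept 36.6% in UNC6852 and 33.9% in UNC1999, against 31.5% and 35.0% between the treated profiles. Contacts that touched none of these genes kept 31.2% and 29.1%, against 29.0% and 31.6%. The homeobox regulators kept 35.7% and 32.7%, the mesoderm and endoderm regulators 32.4% and 31.6%, the neural regulators 30.2% and 26.7%, and the signalling genes 25.3% and 24.1%. Intervals here and below are exact binomial ones and cover counting error only.

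Over all cis contacts, 31.4% (31.0 to 31.7) of the DMSO calls were also called in UNC6852 and 29.3% (28.9 to 29.6) in UNC1999. The treated profiles shared 29.1% of the UNC6852 calls and 31.7% of the UNC1999 calls. As a share of all contacts called in either profile of a pair, overlap was 17.7% for DMSO with UNC6852, 17.2% for DMSO with UNC1999 and 17.9% for UNC6852 with UNC1999. The 3 overlaps lay within 1 percentage point of each other, so DMSO did not stand apart from the treated profiles. With quantile-normalized scores the order changed, to 19.1%, 18.3% and 18.1%. Of the cis pairs, 77.5% were called in 1 profile, 14.1% in 2 and 8.33% in 3. Of the trans pairs, 99.7% were called in 1 profile.

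**Figure D1:**
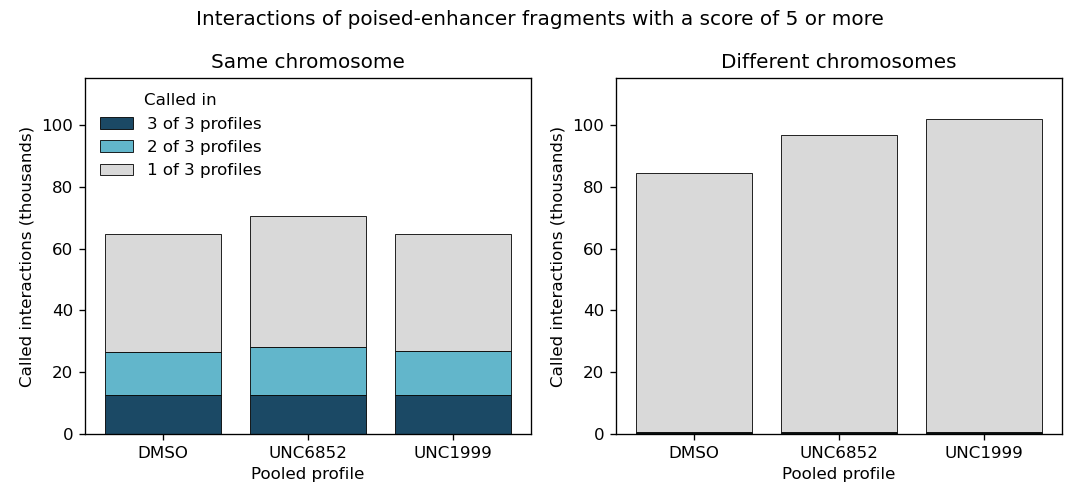
Number of called contacts in each pooled profile, within chromosomes at left and between chromosomes at right, with bars split by whether a contact was called in 1, 2 or 3 profiles. Of listed cis pairs, 8.33% were called in all 3, and 99.7% of trans pairs were called in 1.

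Scores of contacts were compared after an asinh transform, which keeps scores of 0. TFAP2C contacts averaged 2.19 in DMSO, 2.52 in UNC6852 and 2.13 in UNC1999, and HOXA5 contacts averaged 2.12, 2.15 and 2.19. Over all cis pairs the median difference from DMSO was 0.021 in UNC6852, with quartiles of -0.62 and 0.78, and 0 in UNC1999, with quartiles of -0.70 and 0.70. Contacts called in DMSO lay lower in the treated profiles by a median of -0.63 and -0.69. Contacts called in a treated profile lay higher there than in DMSO by 0.70 and 0.69, so each of these values follows from the profile used for selection. When contacts were selected on the profile outside the difference, the median was 0 for each of the 3 contrasts. The mean was then 0.061 for UNC6852 minus DMSO, 0.0048 for UNC1999 minus DMSO and 0.052 for UNC6852 minus UNC1999.

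Distance was examined because poised enhancers reach their genes over long spans. A captured fragment at HOXC6 met a fragment 169 kb away with scores of 26.0 in DMSO, 23.1 in UNC6852 and 33.7 in UNC1999. HOXD8 met a fragment 513 kb away with scores of 25.6, 27.8 and 18.5, and NKX3-2 met a fragment 818 kb away with 25.8, 23.3 and 20.8. FOXA1 met the PAX9 end 931 kb away with 19.5, 16.4 and 13.9. Each of these contacts was called in all 3 profiles, and they were singled out after their values were seen, as the strongest of their lists by mean score. The share of DMSO calls also called in UNC6852 was lower with distance: 46.5% under 20 kb, 42.7% from 20 to 100 kb, 34.3% from 100 to 500 kb, 19.9% from 0.5 to 2 Mb, 12.6% beyond 2 Mb and 0.70% in trans. For UNC1999 these shares were 44.9%, 40.5%, 32.0%, 18.0%, 12.1% and 0.60%. The share of UNC1999 calls also called in UNC6852 ran from 49.9% under 20 kb to 20.2% from 0.5 to 2 Mb and 0.57% in trans. From 0 to 2 Mb, the UNC6852 shares lay between the shares that the treated profiles had of each other. The UNC1999 shares lay just below that range up to 500 kb, by less than their counting intervals. Without the 1% of baits with most pairs, the shares beyond 2 Mb were 5.42% in both treated profiles, and those in trans were 0.37% in UNC6852 and 0.28% in UNC1999.

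**Figure D2:**
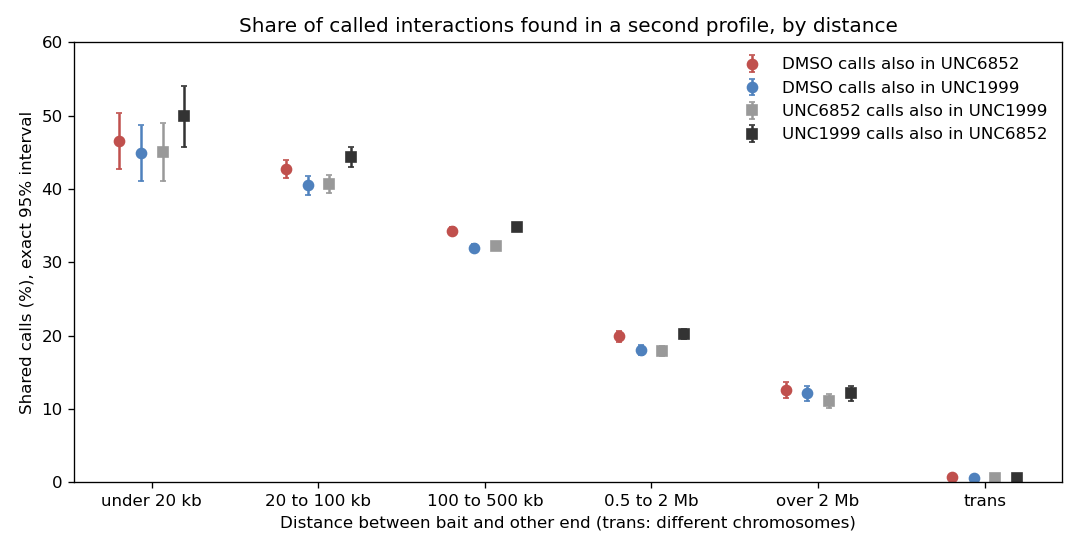
Percent of calls of a profile that were also called in another, by distance between bait and other end (with exact 95% binomial intervals, counting error only). Shares were highest under 20 kb (46.5% for DMSO calls in UNC6852) and lowest in trans (0.70%), and the shares between the treated profiles (squares) lay beside those of the DMSO calls (circles).

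Contacts were then split by what the other end held, to ask whether contacts among captured fragments depend on PRC2 more than those with uncaptured gene ends. Captured fragments can lie at gene ends themselves, so the split does not separate enhancer-to-enhancer from enhancer-to-gene contacts. Among contacts between 2 captured fragments, PAX9 with FOXA1 over 934 kb scored 9.0 in DMSO, 4.28 in UNC6852 and 6.19 in UNC1999, but 0, 10.8 and 2.92 from the adjoining PAX9 bait. HOXB9 with HOXB13 over 103 kb scored 0.50, 0.48 and 7.93. Among contacts with the end of a gene that was not captured, a bait 169 kb from KMT2D scored 9.78, 11.9 and 14.5, and NEUROG1 with PITX1 over 499 kb scored 0, 10.3 and 4.77. These contacts were chosen after their values were seen. Captured other ends made up 4340 cis pairs, with 1719 calls in DMSO, 1989 in UNC6852 and 1767 in UNC1999. Of the DMSO calls, 27.9% (25.8 to 30.1) were also called in UNC6852 and 25.8% (23.8 to 27.97) in UNC1999, against 24.6% and 27.7% between the treated profiles. Gene ends made up 16515 pairs and kept 33.9% (32.8 to 35.0) and 31.1% (30.0 to 32.2). The remaining 131833 pairs kept 31.1% and 29.1%. Against contacts of equal distance and mean score, captured other ends kept 1.16 percentage points more in UNC6852 and 0.62 more in UNC1999. Gene ends kept 0.27 points more and, in UNC1999, a difference of -0.45 points. All of these differences were within the width of the counting intervals. The mean score was taken over all 3 profiles, so it includes the score that decides whether a call was kept. A loss particular to 1 class would thus be partly matched away, and the matched values do not decide the question. In the other direction, gene ends kept 32.2% (31.1 to 33.2) of UNC6852 calls in DMSO, against 30.9% of matched contacts, which lay outside that interval.

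The gene lists addressed whether developmental genes that are targets of Polycomb lose contact strength as a group. For each gene, asinh scores were averaged over the cis pairs that reached within 1000 bp of either of its ends. HOX genes showed no common direction. Of 40 measured, 22 were higher and 18 lower in UNC6852 than in DMSO, with a median difference of 0.048, and 23 were higher and 17 lower in UNC1999, with a median of 0.034. HOXB genes lay mostly higher, with 7 of 9 above DMSO in both treated profiles and medians of 0.19 and 0.074, although with quantile-normalized scores 1 of 9 did and the medians were 0.019 and -0.13. That scaling moved the median of all genes from 0.069 to -0.14 in UNC6852 and from -0.0076 to -0.23 in UNC1999, and relative to it HOXB genes stood at 0.16 and 0.11. HOXD genes had medians of -0.12 and -0.12, with 4 of 9 below DMSO in both and 3 above it in both. HOXA genes had medians of 0.033 and -0.13, and HOXC genes -0.034 and 0.014. Quantile normalization made the positive ones -0.16 for HOXA and -0.22 for HOXC, which relative to all genes stood at -0.016 and 0.0072. HOXD1 (chromosome 2, 176188668 to 176190907, GRCh38) had 54 pairs, 33 of them called in DMSO, 19 in UNC6852 and 21 in UNC1999. Its differences were -0.35 and -0.33. They kept their sign under every alternative setting that was run, but came as close to 0 as -0.11 and -0.14. HOXD12 had differences of -0.39 and -0.18, although the first became 0.10 when gene ends were widened to 5000 bp. HOXB8 had the highest UNC6852 difference of the HOX genes, 0.99 over 6 pairs, with 2 calls in DMSO, 6 in UNC6852 and 2 in UNC1999. HOXA13 was higher by 0.57 in both.

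**Figure D3:**
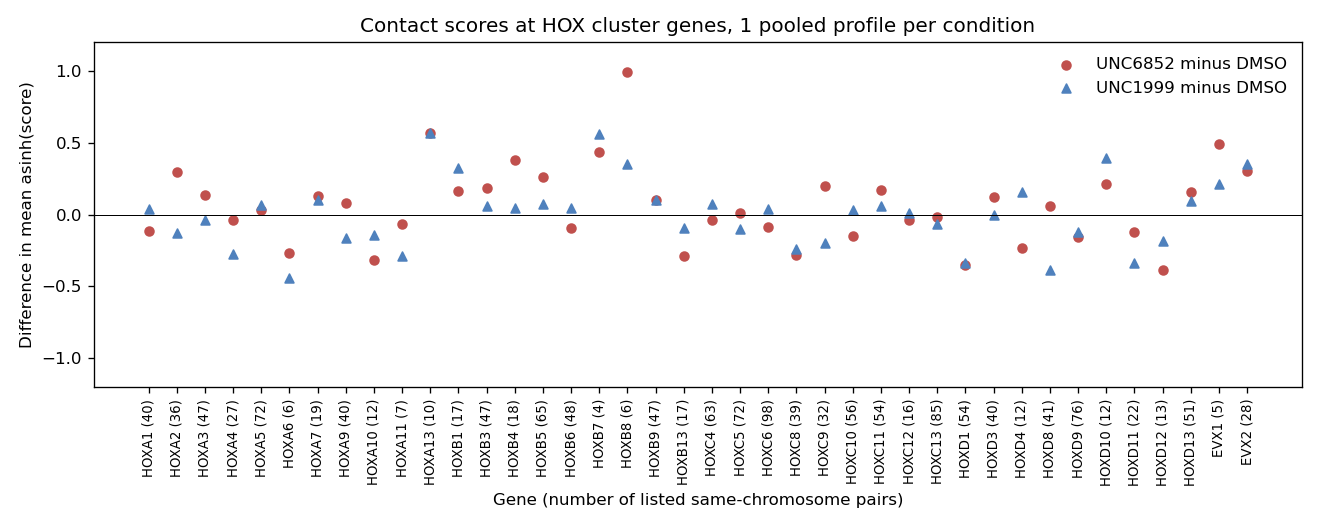
Difference from DMSO in mean asinh score of each of the 40 measured HOX cluster genes, UNC6852 as circles and UNC1999 as triangles, with each gene's number of pairs in brackets. Points lie on both sides of 0, with HOXD1 at -0.35 and -0.33 and HOXB8 at 0.99 and 0.35, the last of which became -0.01 with quantile-normalized scores, when the median of all genes was -0.23.

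The HOX median lay at percentile 40.2 for UNC6852 and 74.6 for UNC1999 among random lists of genes with like scores and numbers of pairs. Homeobox regulators outside the HOX clusters lay higher in UNC6852, with a median of 0.19 and 43 of 64 genes above DMSO. This was the one list median outside the central 95% of random lists, at percentile 98.8 against bounds of -0.040 and 0.17, among 30 comparisons of a list and a contrast. The same list had a median of 0.069 in UNC1999, at percentile 89.8, and 0.075 for UNC6852 minus UNC1999, at percentile 62.1. Its UNC6852 median was -0.052 when only pairs with the gene at the other end were used, and -0.036 with quantile-normalized scores. The latter scaling lowered all genes, and the list lay at percentile 97.45 under it, just inside the central 95%. Its UNC6852 median was outside that range under 5 of 11 alternative settings. POU3F3 was its highest member, with 1.95 over 6 pairs in UNC6852 and 0.093 in UNC1999, and LHX5 its lowest, with -1.02 and 0.32, the first of which became 0.17 with gene ends widened to 5000 bp. Neural and neural crest regulators had medians of 0.022 and 0.0017, with NEUROD1 the highest at 2.03 and 0.26. Regulators of mesoderm and endoderm had medians of 0.075 and 0.066, which with a mean score of at least 5 became 0.20 (percentile 99.25) and 0.14 (percentile 95.75). TBX20 was lowest there at -1.06 and -1.16, the last of which became 0.39 with the gene at the other end only, and FOXQ1 was highest at 1.32 and 0.43, which became -0.33 and -0.21 with a mean score of at least 5. Signalling genes had medians of 0.030 and -6.6e-05, with SFRP5 at -1.06 and -0.41 (the last 0.10 with pairs of up to 2 Mb) and CYP26A1 at 1.85 and 0.16. A shift of -0.2 planted in the HOX genes put their UNC6852 median outside the central 95% in 17 of 20 simulated draws, and a shift of -0.1 in 6 of 20, so smaller list-wide losses would mostly have been missed. With no shift, 2 of 20 draws lay outside. All percentiles describe these pooled profiles and carry no replicate error.

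**Figure D4:**
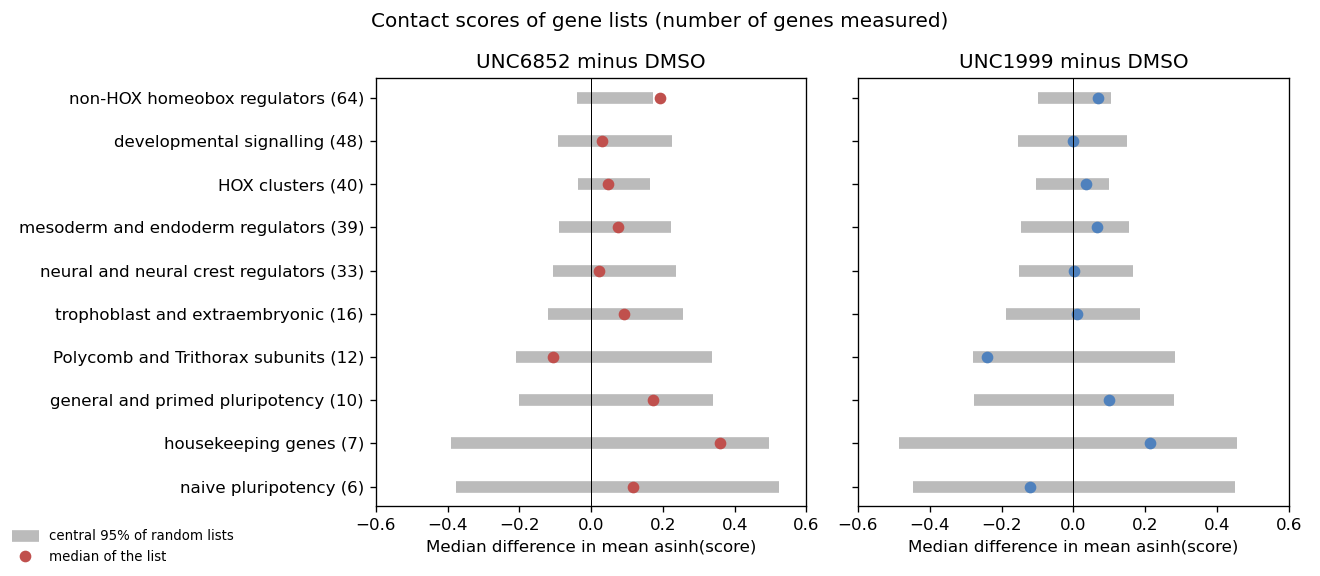
Median difference from DMSO in mean asinh score for the 10 gene lists (points) with the central 95% of random lists of like genes (grey bars), UNC6852 at left and UNC1999 at right. The homeobox regulators in UNC6852, at 0.19, lie outside their bar (with quantile-normalized scores, which lower all genes, that median is -0.036 at percentile 97.45), while the other medians lie inside.

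Lists of cell state genes were examined since the cells were leaving the naive state. TFAP2C had 59 pairs and differences of 0.32 in UNC6852 and -0.070 in UNC1999. TFCP2L1 lay at -0.28 and -1.09, but both became 0.03 when gene ends were widened to 5000 bp. Over all settings its values ran from -2.98 to 0.46 and from -2.98 to 0.034. KLF4 lay at -0.22 and -0.39, and became 0.33 and 0.14 at that width. Only 6 of 29 naive genes were measured, with list medians of 0.12 and -0.12 at percentiles 57.0 and 27.2. With at least 1 pair per gene these medians were -0.24 and 0.17, at percentiles 6.45 and 81.05. The 10 of 30 measured genes of general and primed pluripotency had medians of 0.17 and 0.10 at percentiles 77.0 and 75.9, with DNMT3A at -0.43 and -1.69 over 3 pairs, the first of which became 0.81 with pairs of up to 2 Mb. Trophoblast and extraembryonic genes had medians of 0.091, with 14 of 16 genes higher, and 0.011, with 8 of 16 higher. These medians lay at percentiles 60.2 and 52.0 of random lists. CDX2 lay at -0.20 and -0.090 over 23 pairs, which became 0.19 and 0.07 with gene ends widened to 5000 bp, and IGFBP3 lay at 0.75 and -0.061, the last of which became 0.66 with a mean score of at least 5. The housekeeping list had 7 of 49 genes measured and medians of 0.36 and 0.21, at percentiles 92.0 and 85.7. With at least 1 pair per gene the UNC6852 median was 0.017, and with at least 5 the UNC1999 median was -0.091. The extremes of the list were VPS29 at -1.85 and -1.51 over 4 pairs and TBP at 1.27 and 0.24.

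Genes for Polycomb and Trithorax subunits lay mostly below DMSO, although both differences hold the same DMSO profile and so are not independent. Of 12 measured, 10 were lower in UNC6852, with a median of -0.11, and 11 were lower in UNC1999, with a median of -0.24. CBX6 lay at -1.01 and -0.26, KDM6B at -0.82 and -0.22, and PCGF2 was the highest at 0.61 and 0.28, the last of which became -0.22 with a mean score of at least 5. The medians lay at percentiles 9.5 and 4.6, inside the central 95% of random lists of 12 like genes. The UNC1999 median left that range under 2 of 11 alternative settings, at percentile 2.45 with means over baits and 1.85 with gene bodies. With the gene at the other end only, the UNC6852 median was 0.027 and the UNC1999 median -0.070, and with a mean score of at least 5 they were 0.018 and 0.00089. In simulated draws a planted shift of -0.2 in these genes left that range in 2 of 20 and one of -0.5 in 17 of 20.

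How far a single contact can be trusted was examined from captured fragments that neighbour each other and meet the same other end. A fragment 241 kb from TCF7L1 scored 19.1 with it in DMSO, 20.7 in UNC6852 and 12.3 in UNC1999. Neighbouring captured fragments met the same TCF7L1 end with 16.0, 10.6 and 9.19, and with 8.49, 16.8 and 14.9. A fragment at DKK1 met a fragment 175 kb away with 7.49, 18.1 and 12.4, while its neighbour met the same fragment with 11.9, 12.9 and 11.6. One FOXA1 fragment met PAX9 with 19.5, 16.4 and 13.9, and its neighbour did so with 5.83, 16.9 and 19.2. FOXA1 met the same NKX2-1 fragment over 1073 kb with 7.48, 10.7 and 9.51 from one bait and over 1071 kb with 5.25, 12.5 and 3.48 from the other. Over 21344 such comparisons on 12899 other ends, the differences of neighbours correlated across pairs with r = 0.057 for UNC6852 minus DMSO, 0.050 for UNC1999 minus DMSO and 0.055 for UNC6852 minus UNC1999. With the 3 profile labels exchanged at random in 1 of the 2 neighbours, r lay between -0.017 and 0.013 for the first contrast. The sign was shared in 52.2%, 51.2% and 52.0% of comparisons. Neighbouring fragments thus shared differences only weakly, though above the range of exchanged labels for each contrast. Labels were exchanged anew for each comparison although other ends recur among comparisons. That range is therefore likely too narrow, and lying above it does not settle whether differences were shared. Neighbours shared differences about as much between the treated profiles as against DMSO. No chance value was computed for the shared sign. Pairs are not independent replicates, and this comparison was chosen after the values were seen.

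Individual genes were ranked among the 1633 with at least 5 cis pairs and a mean score above the median. PIGH had the lowest UNC6852 difference, -1.195 over 5 pairs, with 4 calls in DMSO, 0 in UNC6852 and 2 in UNC1999. CCDC9 and INAFM1, which share their fragments, followed at -1.19, but came as close to 0 as -0.0020 under an alternative setting. DEFB126 lay at -1.15 in UNC6852 and -1.09 in UNC1999, with 15 calls in DMSO, 2 in UNC6852 and 0 in UNC1999, though pairs of up to 2 Mb alone gave -0.56 and -0.48 and pairs with the gene at the other end -0.32 and -0.19. ANKZF1 lay at -1.12 and -1.04, but at -0.36 and -0.12 over pairs with a mean score of at least 5. GALR1 lay at -1.07 and -1.19, but at -0.019 and 0.028 when gene ends were widened to 5000 bp. ATF7, its read-through neighbour ATF7-NPFF and NPFF shared fragments and lay at -1.06 (0.02 with gene bodies for the first and second), and CRACR2A at -1.05. The highest UNC6852 values were those of SLC68A1 at 1.35, KCNK16 at 1.23, POLR1B at 1.05, and INPP5A with NKX6-2 at 1.05. The last of these share 16 pairs, 3 called in DMSO, 15 in UNC6852 and 5 in UNC1999. In UNC1999 the lowest genes besides GALR1, DEFB126 and ANKZF1 were CCL16 at -1.16, ARL9 at -1.07, SPATA22 at -1.04, DCD at -1.02 and KRT13 at -1.01, and the highest were IRGM at 1.21, EIF1B at 1.14, CT47C1 at 1.08 and IPO9 at 1.03. CT47C1 became -0.04 with a mean score of at least 5, and IPO9 -0.16 with gene bodies in place of gene ends. Under alternative settings ARL9 came as close to 0 as -0.033, SPATA22 as -0.27 and EIF1B as 0.23. CETN1 at -0.99 and FIBIN at -0.97 (0.48 with a mean score of at least 5) closed the lowest genes, and RPP30 at 0.99 the highest.

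Genes this far apart were about as frequent between the treated profiles as against DMSO. Of 3266 genes with at least 5 pairs, 155 differed by 1 or more in either direction for UNC6852 minus DMSO, 133 for UNC1999 minus DMSO and 156 for UNC6852 minus UNC1999. The standard deviation over these genes was 0.461, 0.455 and 0.472. Of the 112 values of named genes, 54 changed sign under at least 1 alternative setting. These settings include quantile normalization, which lowered all genes together, so a change of sign under it says little about a single gene. The contrast between the treated profiles may hold effects of each compound and is no measure of replicate variation. Without replicate profiles, no gene's difference could be set against such variation.

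The largest falls of single contacts from a DMSO score of at least 10 at a gene end were almost all trans contacts. EPHA2 with PGS1 scored 31.1 in DMSO and 0 in both treated profiles. NEUROD2 with the adjoining ends of GCDH and SYCE2 scored 29.0, 0 and 0. CIART with FAM90A1 scored 29.7, 0 and 12.9. A bait on chromosome 4 with KIF2A scored 28.5, 0 and 0, and a bait on chromosome 5 with CLK1 scored 27.0, 0 and 0. For UNC1999 the list was led by a bait on chromosome 17 (22521401 to 22521558) with the mitochondrial genes CYTB and ND6, at 3653 in DMSO, 1959 in UNC6852 and 0 in UNC1999. Mitochondrial DNA lies outside the nucleus, so this fall cannot be read as an enhancer contact lost, and its source was not tested. A bait 18920 kb from STH scored 29.5, 24.6 and 0. Trans pairs recurred in 0.70% or fewer of calls in any comparison of profiles, so a trans call was seldom called again. The median score of trans pairs called in DMSO was 0 in each treated profile.

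The last comparison asked whether both compounds moved the same genes. HOXD1, DEFB126, ANKZF1 and VPS29 lay below DMSO in both treated profiles, and IRGM, HOXA13 and EVX2 above it in both. Across 4979 genes with at least 3 pairs, the differences of UNC6852 and UNC1999 from DMSO correlated with r = 0.456 and shared their sign in 64.8%. Because both differences contain the same DMSO profile, a correlation arises without any change. In data with the profile labels exchanged at random for each bait, r was 0.500 (0.478 to 0.525 over 100 draws) and the sign was shared in 66.6%. Across cis pairs r was 0.500, against 0.500 (0.496 to 0.503). The covariance over genes was 0.153, against 0.170 (0.158 to 0.182). Over genes, r, the covariance and the shared sign lay below the ranges of the exchanged profiles, which thus did not describe these profiles fully. UNC6852 minus UNC1999 varied most over these genes, with a standard deviation of 0.605 against 0.578 and 0.582 for the differences from DMSO. Agreement beyond that of a common reference profile was not seen, but this comparison cannot exclude a shared effect. Genes and pairs are not independent replicates, and the DMSO profile could not be split.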

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

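Alternatives chosen only after results were seen were gene bodies in place of gene ends, pairs of up to 2 Mb for genes, and kept shares on quantile-normalized scores; the others were planned. No paired analysis was possible because the processed columns are pooled over replicates. For the same reason, leaving out each replicate in turn was not run. Kept shares cannot change under log2, which keeps the order of scores, so that setting gave no kept shares.

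HOX genes stayed near the random lists under most settings. Their UNC6852 median ran from -0.16 to 0.077 and lay outside the central 95% of random lists under 1 of 11 settings, at percentile 2.15 with a mean score of at least 5. Their UNC1999 median ran from -0.17 to 0.034 and lay inside under all 11. Among homeobox regulators outside the HOX clusters, the UNC6852 median changed sign, to -0.052 (percentile 6.75) with the gene at the other end only and to -0.036 (percentile 97.45) with quantile-normalized scores, and it lay outside the central 95% under 5 of 11 settings. With a mean score of at least 5 it was 0.070 (percentile 67.0). In UNC1999 the median of this list became -0.082, -0.17 and -0.041 under these settings. With gene ends widened to 5000 bp it was 0.13 at percentile 99.9, its only setting outside the central 95%. Of 220 list medians under alternatives, 202 moved from the reported value by less than the spread of random lists, and 12 lay outside the central 95%.

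Quantile normalization shifted all genes, to medians of -0.14 and -0.23, which accounts for the lower list medians it gave. These were -0.16 and -0.17 for HOX genes (UNC6852, then UNC1999), -0.20 and -0.25 for signalling genes, -0.18 and -0.18 for mesoderm and endoderm regulators, -0.17 and -0.23 for neural regulators, and -0.10 and -0.19 for trophoblast genes. The median over cis pairs became -0.031 and -0.11. Other list medians that moved were those of mesoderm and endoderm regulators in UNC1999, at -0.22 with the gene at the other end only, and of primed pluripotency genes in UNC6852, at -0.11 with a mean score of at least 5. The cause was not tested for those 2.

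Named genes depended more on the settings. Of 112 values (56 genes, 2 compounds), 58 kept their sign under every setting that gave a value, among them HOXD1, ANKZF1, DEFB126, CBX6 and VPS29 for both compounds, and 54 changed sign under at least 1. Quantile normalization, which lowered all genes together, is among these settings. Under it small positive values change sign more readily than negative ones. Of 950 values under alternatives, 801 stayed within 0.472, the standard deviation of UNC6852 minus UNC1999 over genes. DEFB126 lay at -0.56 and -0.48 with pairs of up to 2 Mb and at -0.32 and -0.19 with the gene at the other end only, and GALR1 at -0.019 and 0.028 with gene ends widened to 5000 bp. NEUROD2 in UNC6852 went from -0.71 to 0.75 without the top 1% of baits.

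Calls in DMSO, UNC6852 and UNC1999 numbered 32555, 38598 and 35571 at a threshold of 7, 10688, 12211 and 11854 at 10, and 64068, 69794 and 63979 for cis pairs of at least 20 kb, since each of these settings admits fewer pairs. The other 12 counts stayed within 1.5 times the reported ones.

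Kept shares are given as DMSO calls in UNC6852, DMSO calls in UNC1999 and UNC1999 calls in UNC6852. For cis pairs they were 36.4%, 34.1% and 36.3% at a threshold of 7, 44.3%, 41.9% and 43.6% at 10, 30.1%, 27.9% and 32.3% with equal numbers of calls, 37.7%, 35.9% and 37.9% with merged fragments, and 29.9%, 27.96% and 30.3% without the top 1% of baits. With quantile-normalized scores the last was 32.3%. For all listed pairs they were 22.6%, 21.3% and 21.2% at 7, 23.7%, 22.6% and 22.5% at 10, 13.5%, 12.4% and 12.9% with equal numbers, 12.9%, 12.3% and 11.3% merged, 31.2%, 29.1% and 31.6% for cis pairs of at least 20 kb, which leave out trans pairs, and 13.0%, 12.1% and 11.7% without the top 1% of baits. Quantile normalization gave 14.4% for the first and 12.9% for the last. For cis pairs, overlap between the treated profiles was at least that of either with DMSO under 7 of 8 alternatives, and below it (18.1% against 19.1% and 18.3%) with quantile-normalized scores. The cause of these moves was not tested.

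By class of other end, captured fragments kept 53.5% in UNC6852 and 52.4% in UNC1999 with merged fragments, 70.6% and 67.9% with a mean score of at least 5, and 25.6% and 23.1% without the top 1% of baits. Gene ends kept 55.6% and 52.9%, 75.4% and 70.8%, and 32.5% and 29.9% under these settings. By distance, leaving out the top 1% of baits gave 41.3% in UNC6852 from 20 to 100 kb, 32.9% and 30.8% from 100 to 500 kb, 18.7% and 17.0% from 0.5 to 2 Mb, 5.42% and 5.42% beyond 2 Mb, and 0.37% and 0.28% in trans. With a mean score of at least 5, the median difference over cis pairs was 0.050 in UNC6852 and 0.016 in UNC1999, and the treatments correlated with r = 0.509 over pairs and 0.504 over genes. The cause of the other moves was not tested. Unknown depth of the profiles limits all of these values, since no setting can correct for it.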

Other observations

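Tests chosen only after the result was seen were those of specific trans contacts, of depth and of HOX loss; the others were written down before their result.

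Contacts between developmental genes were few and varied between the profiles. From 100 kb to 2 Mb, 35 pairs joined ends of genes of the 5 developmental lists, with 17 calls in DMSO, 21 in UNC6852 and 16 in UNC1999. These counts include pairs that joined both ends of a single gene, MEIS2 over 212 and 210 kb and EBF1 over 404 kb. Each of those was called in DMSO. Of the DMSO calls, 9 were also called in UNC6852 and 8 in UNC1999, and 6 of the UNC6852 calls were called in UNC1999. FOXA1 met PAX9 over 931 kb at 19.5, 16.4 and 13.9, and NKX2-1 over 1073 kb at 7.48, 10.7 and 9.51. VAX1 met EMX2 over 409 kb at 7.34, 4.19 and 5.12. Adjoining VAX1 baits met other EMX2 fragments, over 402 kb at 0.77, 7.42 and 0.95 and over 411 kb at 0.97, 5.76 and 0.79. From baits at EMX2, contacts with VAX1 scored 3.47, 6.21 and 5.72 over 422 kb and 0, 5.61 and 0 over 404 kb. FGF5 met BMP3 over 762 kb at 3.88, 5.98 and 4.2. IRX5 met IRX3 over 644 kb at 1.10, 5.61 and 6.97, and a neighbouring bait met another IRX3 fragment over 648 kb at 5.58, 5.41 and 0. In trans, 15 pairs joined such genes and 0 were called in more than 1 profile. These pairs were chosen after their values were seen.

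HOXD1 lay at -0.35 and -0.33 from DMSO over 54 pairs. Among the 268 genes with at least 30 pairs, DMSO lay above both other profiles by as much in 3 genes, UNC6852 in 7 and UNC1999 in 2. In the other direction, DMSO lay below both others in 8, UNC6852 in 0 and UNC1999 in 5. Profiles were not centred, and the median difference of UNC6852 from DMSO over all genes was 0.069. Chance values of the 1 shared DMSO profile may be enough, but these counts do not decide it. Loss of HOX contacts on PRC2 perturbation would put most HOX genes below DMSO in both, and 27.5% (14.6 to 43.9) of 40 were, 11 genes against 16 above DMSO in both. With profiles exchanged at random for each bait the share was 33.8% (18.7 to 50.1 over 100 draws). The bound of 25% first set for no loss was wrong, since both differences hold the same DMSO profile. Neighbouring HOX genes share fragments, so the test does not decide, and a loss at HOXD1 stays open.

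Trans calls exceeded those of DMSO by 12271 in UNC6852 and 17380 in UNC1999. Specific trans contacts gained on PRC2 perturbation would be called in both treated profiles and not in DMSO, and 209 pairs were, or 1.70% (1.48 to 1.95) of the smaller excess, beside 223 shared by DMSO and UNC6852 alone. Since at most 0.70% of trans calls of any profile recurred in another, gained contacts could be missed, and this explanation stays open. Greater depth of the treated profiles could raise calls, but the lower ratio of cis calls was 0.997, in UNC1999. Without replicate profiles or read numbers, depth cannot be told apart from other differences between libraries.

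Captured pairs beyond 2 Mb recurred more than other far pairs, with 49.7% of DMSO calls also called in UNC6852 and 55.8% in UNC1999, against 10.7% and 9.96%. Of 123 recurring ones, 89 (72.4%) joined the intervals 34592190 to 34959566 and 46385643 to 46466530 of chromosome 16, without which the shares were 25.5% and 32.7%. Contacts between developmental gene loci could be a source, but 0 of 123 (up to 2.95%) touched a developmental list gene, against 20 of 324 (6.17%, 3.81 to 9.37) called once. The 123 pairs are not independent, since 89 join the same intervals, so the bound of 2.95% is likely too low. Only fragments within 1000 bp of a gene end were counted, so contacts of more distant elements of these loci are not excluded. Reads shared between near-identical sequences may be a source, but the 42 baits had a median of 9 (7 to 11) listed trans pairs, like the 9 of all baits, which does not decide it. A median can hide single baits with many partners. Baits starting at 46390065 and 46390694, within the second chromosome 16 interval, had 153 and 41 listed trans pairs. The interval on that median was added after the value was seen.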
